A study of Mus musculus with 2 samples.

How the data were processed

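DNase-seq was done on lung tissue of 2 female B6CASTF1/J mice, each 2 months old, in 1 library per animal. Per the labels the libraries come from separate biosamples and are biological replicates 1 and 2 of 1 experiment, and both biosamples name the same donor entry, which describes the hybrid strain. The samples were taken as 1 group, lung, with 2 replicates, and the labels name no treatment, batch or date. No paired analysis was possible because the study has a single group and no second measurement of the same animal.

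The authors deposited, for each library separately, 2 lists of peaks, a list of footprints, a list of sites with a false discovery rate (FDR) and a text list of these files with their inputs. Positions are on mm10 per the labels. Each deposited peak carries the authors' own signal value, the height of the cleavage density at the peak, used here only to describe, rank and filter peaks. Within each library the heights come in fixed steps, of 0.00518 in replicate 1 and 0.00600 in replicate 2, a ratio of 1.16. Such steps fit a scaling to library size, but the scale of the heights was not given in the sources used here. Means over the animals use the heights as deposited, and differences between the animals are given relative to the median difference of all genes or peaks, or beside it. Per the labels and the values, the deposited site file gives the FDR of the local cleavage rate, used as a q-value, for sites up to 0.05, and every deposited footprint carries the same limit of 0.01 (a p-value column with a single value). The peak caller, the footprint caller, their versions and the number of reads were not given in the sources used here, so no interval or floor per peak could be computed. Intervals on shares and ratios below cover counting error only. Every peak of the shorter list touched a site with an FDR of at most 0.001, while 67.1% and 68.0% of the longer list did, and 98.7% and 98.5% of the shorter list touched the longer. The longer list was used throughout and the shorter as an alternative. Of the peaks, 2 in replicate 1 and 3 in replicate 2 held unknown bases of the reference, and none ran past the end of a chromosome.

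The reference was the GRCm38.p6 sequence with GENCODE vM21 genes. A peak was assigned to a promoter when it lay within 1 kb of any annotated transcript start of any gene, and otherwise to an exon, an intron or intergenic sequence in that order. A gene had a promoter peak when a peak lay within 1 kb of any of its own starts, and its promoter height was that of the highest such peak, which was the same (overlapping) peak in both animals for 94.4% of the 15031 coding genes open in both. Deposited peaks may overlap each other within a list. Peaks per 100 kb were counted over the gene body and 10 kb on either side, or 2 kb for the Hox genes, where counts and lengths were summed over the group. Olfactory and vomeronasal receptor genes were recognised by their symbols. Shares in single libraries have exact (Clopper-Pearson) 95% intervals. With 2 libraries in 1 group no test of a difference was possible, so values are given per replicate and as mean ± SD (n = 2), where an SD from 2 values is itself imprecise.

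Overlap was counted from 1 shared base. As a reference, the other list was shifted along each chromosome by a random distance 100 times, or 20 times for the location shares, and footprints were shifted 100 times within the regions open in both animals. A peak was called present in a single animal when no peak of the other lay within 1 kb. Heights of overlapping peaks were compared with Spearman's rho.

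Before the data were examined, 42 lists with 533 genes, the motifs, the settings above, the alternatives and the rule for naming genes were fixed. All 533 genes were found in the annotation, 1 of them under another symbol (Dnai1 as Dnaic1), and 4 are non-coding (5530601H04Rik, Ftx, Jpx and Xist). The lung lists cover alveolar type 2, alveolar type 1, club, ciliated, basal and neuroendocrine epithelium, vascular, capillary and lymphatic endothelium, fibroblasts, smooth muscle and pericytes, mesothelium, macrophages, T and NK cells, B cells, neutrophils and monocytes, and lung lineage transcription factors. The lists for other organs cover erythroid cells, heart, liver, neuron, skeletal muscle, thymus, skin, intestine, pancreas, kidney, male germ cells, photoreceptors and fat. The remaining lists cover 7 processes, X-linked and Y-linked genes and 3 groups of Hox paralogues. Each list was compared with 10000 random lists of coding genes, matched on quintiles of the CpG observed over expected ratio within 500 bases of the start for promoter peaks, and on quintiles of gene length for peaks per 100 kb. Percentiles among random lists are descriptions, not tests. The rule named up to 4 members per list with the highest mean promoter height and up to 3, in alphabetical order, with no promoter peak in either lung. It also named the 10 coding genes with the most peaks, the 10 highest distal peaks shared by the animals by mean rank, the 5 highest peaks of each animal alone, the 8 motifs with the highest mean ratio and every motif with a ratio under 1 in both lungs. Not every gene that the rule selects is printed. Any other gene named in the closing section was chosen after its values were seen.

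The 34 motifs were short consensus sequences searched on both strands without mismatches, such as GCGCATGCGC for NRF1, TGACGTCA for CRE and GTCACGTG for the USF-type E-box. Matches per kb in footprints were divided by matches per kb in the rest of the same peaks. For distal peaks, over 1 kb from any start, the divisor was matches per kb in windows of the same width moved 10 kb to a random side and touching no peak. Each motif read backwards without complementing served as a control for base composition. A control has no value where the reversed motif had no match to divide by or, for the SP and KLF motif, reads the same reversed. Ratios have exact 95% intervals. Where the windows held no match, their count was set to 3 for the ratio, while the interval keeps the count of 0; this floor was added after the counts of 0 were seen, and it raised the number of motifs denser in distal peaks by 1, through REST.

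Copies of a peak elsewhere were searched with blastn, word size 28 against the chromosomes and 16 against the mitochondrial genome. A copy needed 90% identity over 80% of the peak, and a mitochondrial match 90% identity over 50 bases. The Y chromosome was compared with 200 random windows on Y of the same widths. For the ratio of promoter heights between the animals, lists with at least 5 members open in both were compared with 10000 random lists matched on 10 classes of height. As an alternative added after the data were seen, this was repeated with only the genes whose highest peak overlaps between the animals. Peaks holding a motif were compared with 1000 random sets of shared distal peaks matched on 10 classes of height.

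The alternatives chosen beforehand were the shorter peak list, the higher 50% of peaks by height, equal numbers of peaks, sites merged at stricter FDR limits, an overlap of 50% of both intervals, promoter windows of 500 bases and 2 kb, flanks of 2 kb, 10 kb and 50 kb, lists without genes that stand in more than 1, densities per coding gene, footprints inside peaks alone, motif thresholds of 1.5 and 3, other motif backgrounds and leaving out each replicate. Transcript starts of the GENCODE basic set, the lung minus other-organ difference beyond random genes matched on CpG content, and the bases covered by peaks in the Hox domains were added as alternatives after the data were seen. The overlap, list and motif counts were tested on simulated data with planted values, and every planted count was recovered, while 10 of 200 null lists fell outside the middle 95% of random lists. Raw reads and allele-specific signal were not analysed here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1, bedtools 2.31.1 and blastn 2.17.0.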

Results

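Open chromatin was mapped by DNase-seq in the lungs of 2 female mice, each 2 months old and each an F1 hybrid of the C57BL/6 and CAST/Ei strains (B6CASTF1/J). DNase I cleaves accessible DNA, so a dense cluster of cleavages (a peak) marks an open promoter or enhancer, and a short protected stretch inside it (a footprint) marks a bound protein. The labels name no treatment, and the libraries form 1 group of 2 biological replicates, with no condition to compare. The values below therefore describe which genes and regions were open in the lung and how far the 2 animals resembled each other. The deposited lists held 140311 peaks in replicate 1 and 145721 in replicate 2, a mean of 143016 ± 3825 (SD, n = 2). The peaks covered 29.4 Mb of the mm10 genome in replicate 1 and 31.8 Mb in replicate 2, with a median width of 200 bases in each. Read totals were not given in the sources used here, so the depth behind each peak is unknown. The mm10 sequence is that of C57BL/6, and whether reads of the CAST/Ei alleles mapped less well, which would lower or remove peaks, could not be tested from peak lists. Sites at a false discovery rate of at most 0.05 covered 48.0 Mb in replicate 1 and 53.6 Mb in replicate 2. At a limit of 0.01 they covered 38.8 Mb and 43.3 Mb, and at 0.001 they covered 30.9 Mb and 34.3 Mb.

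The open regions of the 2 lungs were largely the same, and the strongest were shared almost completely. Among the highest 10% of peaks by height, 99.2% of those of replicate 1 and 99.5% of those of replicate 2 touched a peak of the other animal. Among the lowest 10% the shares were 37.3% and 29.2%. Over all peaks, 79.2% in replicate 1 and 75.7% in replicate 2 were shared. The same overlap after circular shifts of the other list was 2.34% and 2.25%, so the observed sharing was 33.9-fold and 33.7-fold higher. Across 111164 pairs of overlapping peaks, heights had a Spearman's rho of 0.911. This rank correlation is across peaks, which are not independent replicates. Heights in replicate 2 were higher by a median of 0.15 on the log2 scale, and 95.1% of pairs lay within 2-fold of each other.

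**Figure D1:**
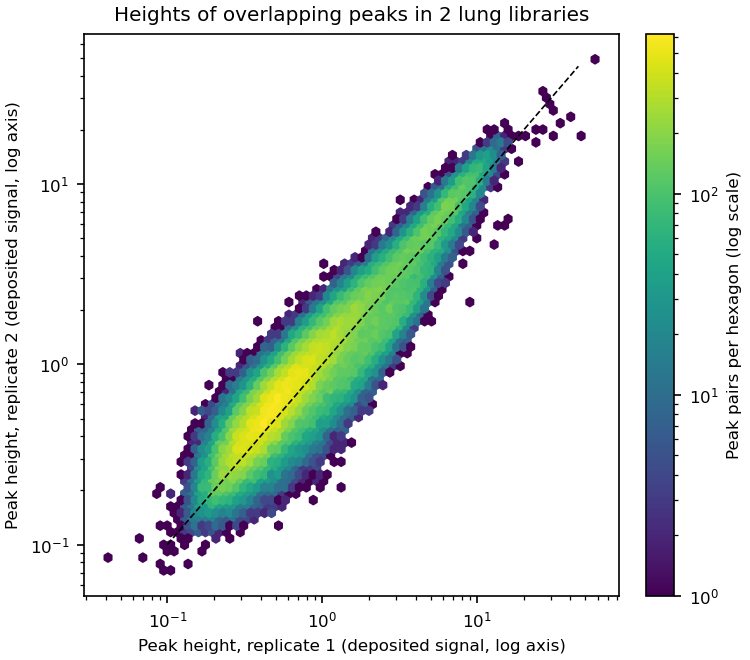
Height of each overlapping peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the units of the deposited signal, with colour giving the number of peak pairs per hexagon. The 111164 pairs scatter along the dashed line of equal heights with a Spearman's rho of 0.911.

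Peaks found in a single animal were low, and the highest of them lay outside promoters. Replicate 1 had 15889 peaks (11.3%) with no peak of the other animal within 1 kb, and replicate 2 had 22665 (15.6%). Their median heights were 0.274 and 0.294, against 0.647 and 0.714 for the remaining peaks. The highest of them in replicate 1 lay near Eif1 (chromosome 11, 100300421 to 100300580, height 2.27), near the X-linked Gm21887, at Pnpla2 and Kat8, and 20529 bases from the start of the surfactant protein gene Sftpb (chromosome 6, 72284001 to 72284160, height 1.81). The highest in replicate 2 lay near Btg2 (chromosome 1, 134065194 to 134065640, height 1.67), near Ptk2 and Gm9887, inside Nfix with G430095P16Rik as the nearest start, and 2602 bases from Cebpa (chromosome 7, 35116581 to 35116800, height 1.51). The peak near Gm21887 has 18 further copies on the chromosomes at 90% identity, and the other 9 have none.

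Promoters held far more peaks than shifted lists did, and promoter peaks had the highest median height of the 4 places compared. Peaks within 1 kb of an annotated transcription start made up 29.9% of replicate 1 (exact 95% interval 29.7 to 30.2%) and 27.6% of replicate 2 (27.4 to 27.8%), a mean of 28.8% ± 1.66 (SD, n = 2). Shifted peaks fell there in 6.65% and 6.72% of cases, so promoters held 4.5-fold and 4.11-fold more peaks than shifted ones. Median heights were 0.947 and 1.07 at promoters, against 0.497 and 0.534 in introns and 0.471 and 0.492 between genes. Introns held 35.3% and 36.7% of peaks, intergenic sequence 29.1% and 30.0%, and exons 5.61% and 5.69%.

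Of 21938 protein-coding genes, 15369 in replicate 1 and 15395 in replicate 2 had a promoter peak, and 15031 had it in both lungs. The shares were lower for long non-coding RNA genes (37.0% ± 0.126, SD, n = 2), microRNA genes (20.3% ± 0.45) and pseudogenes (6.63% ± 0.193). Olfactory and vomeronasal receptor genes, which serve smell in the nose, were almost all closed, with 26 and 33 of 1464 open. Openness followed the CpG content of the promoter. In the quintile of coding genes with the fewest CpG dinucleotides 19.9% of replicate 1 and 20.9% of replicate 2 had a promoter peak, and in the richest quintile 98.2% and 98.1% did. Gene lists were therefore compared with 10000 random lists of coding genes of the same size and the same CpG quintiles. Heights of named genes below are those of the highest promoter peak in each animal. For Vegfa, Itga6, Nr2f2, Notch3, Itgax, Ly6c2, Elf3 and Per1 this was a different peak in each animal. Their SD is therefore not the spread of a single site.

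Marker genes of lung cell types were open more often than all coding genes (70.1% and 70.2%), and markers of other organs less often. Of 225 genes in 17 lung lists, 74.2% had a promoter peak in replicate 1 and 77.3% in replicate 2. Of 163 genes in 13 lists for other organs, 38.7% and 36.8% did. The difference of 38.0 percentage points ± 3.50 (SD, n = 2) was far larger than the spread between the animals. Random coding genes matched on the CpG content of each set stood at 60.7% ± 0.177 for the lung genes and 52.7% ± 0.335 for the others, a difference of 7.90 ± 0.158 points, and 30.1 ± 3.66 points remained beyond it. Peaks in and around the genes, their promoter peaks included, showed the same order for the pooled lists, though not for each list. The median lung gene held 12.8 and 13 peaks per 100 kb of gene body and 10 kb flanks, against 6.81 and 6.78 for other organs and 9.50 over all coding genes. That difference of 6.11 ± 0.175 (SD, n = 2) became 2.97 with flanks of 50 kb and 3.64 with the higher 50% of peaks. Some lung lists had medians under 9.50: lymphatic 3.55, B cell 6.65, macrophage 6.80, mesothelium 7.15, T and NK cell 7.17, and neutrophil and monocyte 7.34. Among lists for other organs, the adipocyte list alone lay above 9.50, at 17.8.

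The alveolar epithelium was fully represented. All 15 markers of alveolar type 2 cells, which make surfactant, had a promoter peak in both lungs, against means of 7.90 and 7.99 in matched random lists. The highest promoter peaks of this list belonged to Etv5, an ETS factor of type 2 cells (chromosome 16, 22381309 to 22439719; height 9.28 ± 1.91, SD, n = 2), and to Abca3, the phospholipid transporter of lamellar bodies (8.25 ± 0.691), whose peak also lies within 1 kb of the start of Abca17. Fasn, the fatty acid synthase, reached 6.42 ± 0.508 and the mucin gene Muc1 5.25 ± 0.389. All 15 markers of the flat, gas-exchanging type 1 cells were open as well, against a random mean of 11.3 in each lung. Vegfa, the vascular growth factor, led with 6.23 ± 0.401, ahead of Rtkn2 (3.84 ± 0.342), Cav1 (3.68 ± 0.143), which encodes the coat protein of caveolae, and Gprc5a (3.42 ± 0.753). The type 2 list held a median of 19.2 ± 1.89 peaks per 100 kb and the type 1 list 15.8 ± 0.687, at percentiles 98.5 and 99.8, and 96.7 and 98.1, of random lists matched on gene length.

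In airway epithelium the secretory markers were open more often than matched random lists, and the ciliated, basal and neuroendocrine markers were near them. Club and secretory markers had promoter peaks for 11 of 15 genes in replicate 1 and 13 of 15 in replicate 2, where CpG-poor promoters gave random means of only 5.12 and 5.20. Por, which feeds electrons to cytochrome P450 enzymes, reached 13.7 ± 2.45 (chromosome 5, 135670033 to 135735326), and Selenbp1, Cyp4b1 and Cbr2 reached 6.45 ± 1.65, 4.63 ± 0.331 and 2.62 ± 0.0141. Bpifa1 had no promoter peak. Ciliated cell markers were open for 14 of 15 genes in each lung, near the random mean of 12.5. Rsph1, a radial spoke protein of motile cilia, reached 12.8 ± 0.889, the dynein chain gene Dnaic1 10.5 ± 2.27 with the start of Fam219a within 1 kb, the ciliogenesis factor Rfx2 9.40 ± 1.04 and Tppp3 8.28 ± 1.60. Dnah5 was the ciliated marker with no promoter peak. Basal cell markers were open for 6 of 11 genes in each lung, against random means of 6.73 and 6.79. Cdh3 (2.90 ± 0.263), Itga6 (2.46 ± 0.430), Snai2 (2.44 ± 0.0288) and Aqp3 (1.061 ± 0.0231) were highest, and the keratin genes Krt14 and Krt15 and Dapl1 were without a peak. Neuroendocrine markers were open for 7 and 8 of 8 genes, near the random mean of 7.07 and 7.06, with low heights for Chga (1.17 ± 0.314), Syp (1.00 ± 0.0374), Scg2 (0.731 ± 0.211) and Resp18 (0.685 ± 0.349).

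Markers of vascular and capillary endothelium were open more often than matched random lists, and lymphatic markers were not. General endothelial markers had promoter peaks for 14 and 15 of 15 genes, against a random mean of 10.3, and markers of lung capillary subtypes for 14 and 15 of 15, against 11.5. The capillary subtype list held a median of 24.2 ± 0.854 peaks per 100 kb and the endothelial list 17.7 ± 1.95, at percentile 99.0 or above of length-matched lists in each lung. Esam, an endothelial adhesion molecule, reached 4.91 ± 0.803, Egfl7 2.87 ± 0.0308 with the start of Gm20532 nearby, the tight junction gene Cldn5 2.41 ± 0.428 and the VEGF receptor gene Flt1 2.39 ± 0.0225. In the capillary list Prx led with 11 ± 1.75, followed by the T-box genes Tbx3 (4.21 ± 0.821) and Tbx2 (2.73 ± 0.45) and the receptor gene Calcrl (2.69 ± 0.477). Lymphatic markers were open for 7 of 9 genes in each lung, near the random mean of 7.11 and 7.10, but with a median of only 3.55 peaks per 100 kb, at percentiles 1.77 and 1.71. Lyve1 (1.1 ± 0.0758), Nr2f2 (1.09 ± 0.0467), the lymphatic regulator Prox1 (1.07 ± 0.0723) and Sema3d (1.065 ± 0.156) had similar heights. Ccl21a and Mmrn1 were closed.

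Supporting cells were open to an intermediate degree. Fibroblast markers had promoter peaks for 11 and 13 of 15 genes, against random means of 9.35 and 9.38, with the collagen gene Col1a1 at 5.02 ± 0.526, the Hedgehog effector Gli1 at 4.01 ± 0.0211, Limch1 at 2.96 ± 0.0805 and the growth factor receptor Pdgfra at 2.65 ± 0.757. Lum and Pi16 had none. Smooth muscle and pericyte markers were open for 12 and 11 of 15 genes, against 9.05 and 9.09, with Myh11 at 2.34 ± 0.750, Tagln at 2.12 ± 0.271, Notch3 at 1.15 ± 0.206 and Pdgfrb at 0.923 ± 0.0608, and with Actg2, Higd1b and Postn closed. The mesothelial list, for the outer lining of the lung, was open for 5 and 4 of 8 genes, against 4.24 and 4.23. Krt19, which other epithelia also express, stood at 3.44 ± 0.944, while Upk1b (0.465 ± 0.0459), Wt1 (0.444 ± 0.0345) and Msln (0.280 ± 0.395) were low. Msln had its peak in replicate 1 alone, and Gpm6a, Muc16 and Upk3b had none.

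Immune cell markers were open only in part. Macrophage markers had promoter peaks for 7 and 9 of 15 genes, against random means of 6.64 and 6.71. Pparg, a regulator of alveolar macrophages that other cells also use, was highest at 1.89 ± 0.425. Car4, which also stands in the list of lung capillary subtypes, followed at 0.879 ± 0.0460, then Itgax at 0.425 ± 0.00682 and Adgre1 at 0.415 ± 0.0157. C1qb, Csf1r and Cx3cr1 had no promoter peak. T and NK cell markers were open for 5 and 4 of 15 genes, against 6.19 and 6.25, with the kinase gene Lck at 4.56 ± 0.366, Tcf7 at 1.54 ± 0.173, Cd2 at 1.39 ± 0.452 and Cd3d at 0.538 ± 0.0304, and with Cd3g, Cd4 and Cd8a closed. B cell markers were open for 7 of 12 genes in each lung, against 4.74 and 4.82. Cd22 (2.31 ± 0.797), Pax5 (2.23 ± 0.207) and Ebf1 (1.76 ± 0.101), of which the last 2 direct B cell identity, were higher than Cd79b (1.05 ± 0.270), and Blk and Cd79a had none. Neutrophil and monocyte markers were open for 3 and 4 of 13 genes, against 3.78 and 3.92. S100a8 (0.479 ± 0.143) and Ly6c2 (0.266 ± 0.0116) were open in both lungs, Mmp8 and Fcgr4 in replicate 2 alone, and Ccr2, Csf3r and Cxcr2 in neither.

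The transcription factors that lay down lung lineages stood out by the number of sites around them. All 20 had a promoter peak in each lung, against a random mean of 18.3, and their domains held a median of 29.7 ± 0.0522 peaks per 100 kb (SD, n = 2) against 9.25 and 9.15 in length-matched lists, at percentile 100 in each. Cebpa, a regulator of type 2 cells, had the highest promoter peak at 8.06 ± 0.418 (chromosome 7, 35119293 to 35121928), followed by Klf5 at 6.42 ± 1.91, Elf3 at 4.58 ± 0.992 and Tbx3.

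Lists for other organs were closed to different degrees. The lowest against random lists were hepatocyte markers, with 2 and 4 of 17 genes open against random means of 7.32 and 7.42, and male germ cell markers, with 4 and 5 of 14 against 8.66 in each. Pancreas markers followed with 4 of 12 in each lung, against 7.10 and 7.14. Among hepatocyte genes Apoa2 had the highest promoter peak (1.12 ± 0.246), Hpx and Fga were open in replicate 2 alone, albumin (Alb) stood at 0.250 ± 0.00250, and Ahsg, Apoa1 and Apoc3 were closed. In the germ cell list Dazl (4.61 ± 0.759) and Zpbp (3.95 ± 0.638, beside the start of Spata48) were high, Akap4 and Ddx4 low, and Acrv1, Odf1 and Prm1 closed. The pancreas list had peaks at Rbpjl, Cela1, Nkx6-1 and Pdx1 and none at Cel, Cpa1 and Ctrb1. Erythroid markers were open for 3 of 12 genes in each lung, with Tal1 and Epor open and Alas2, Ermap and Gata1 closed, against 5.04 and 5.09. Intestinal markers were open for 3 of 10 genes in each lung, against 4.94 and 5.01, and photoreceptor markers for 4 of 13, against 6.00 and 6.09. Thymocyte markers were open for 3 and 2 of 8, against 4.11 and 4.15, and kidney tubule markers for 5 and 3 of 12, against 6.10 and 6.17. Skeletal muscle markers were open for 7 and 6 of 15 genes, against 8.45 and 8.49, with the highest peaks at Actn3, Mylpf and Ckm, each beside the start of another coding gene. The remaining 4 lists lay near their random means. Keratinocyte markers were open for 3 of 10 genes in each lung, against 3.55 and 3.64. Cardiomyocyte markers were open for 7 and 8 of 15, against 7.92 and 8.02, with Myl4 (11.6 ± 1.09) beside the start of Cdc27 and with Actc1, Myh6 and Nppa closed. Adipocyte markers were open for 6 and 5 of 10 genes, against 5.22 and 5.27, with Plin1 at 1.68 ± 0.710 and Adipoq, Cfd and Lep closed. Neuron markers, which have CpG-rich promoters, were open for 12 and 10 of 15 genes, against 11.2 in each lung, with Rbfox3 at 2.00 ± 0.625 and Snap25 at 1.77 ± 0.763, although Nefl, Neurod1 and Neurod2 had none.

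**Figure D2:**
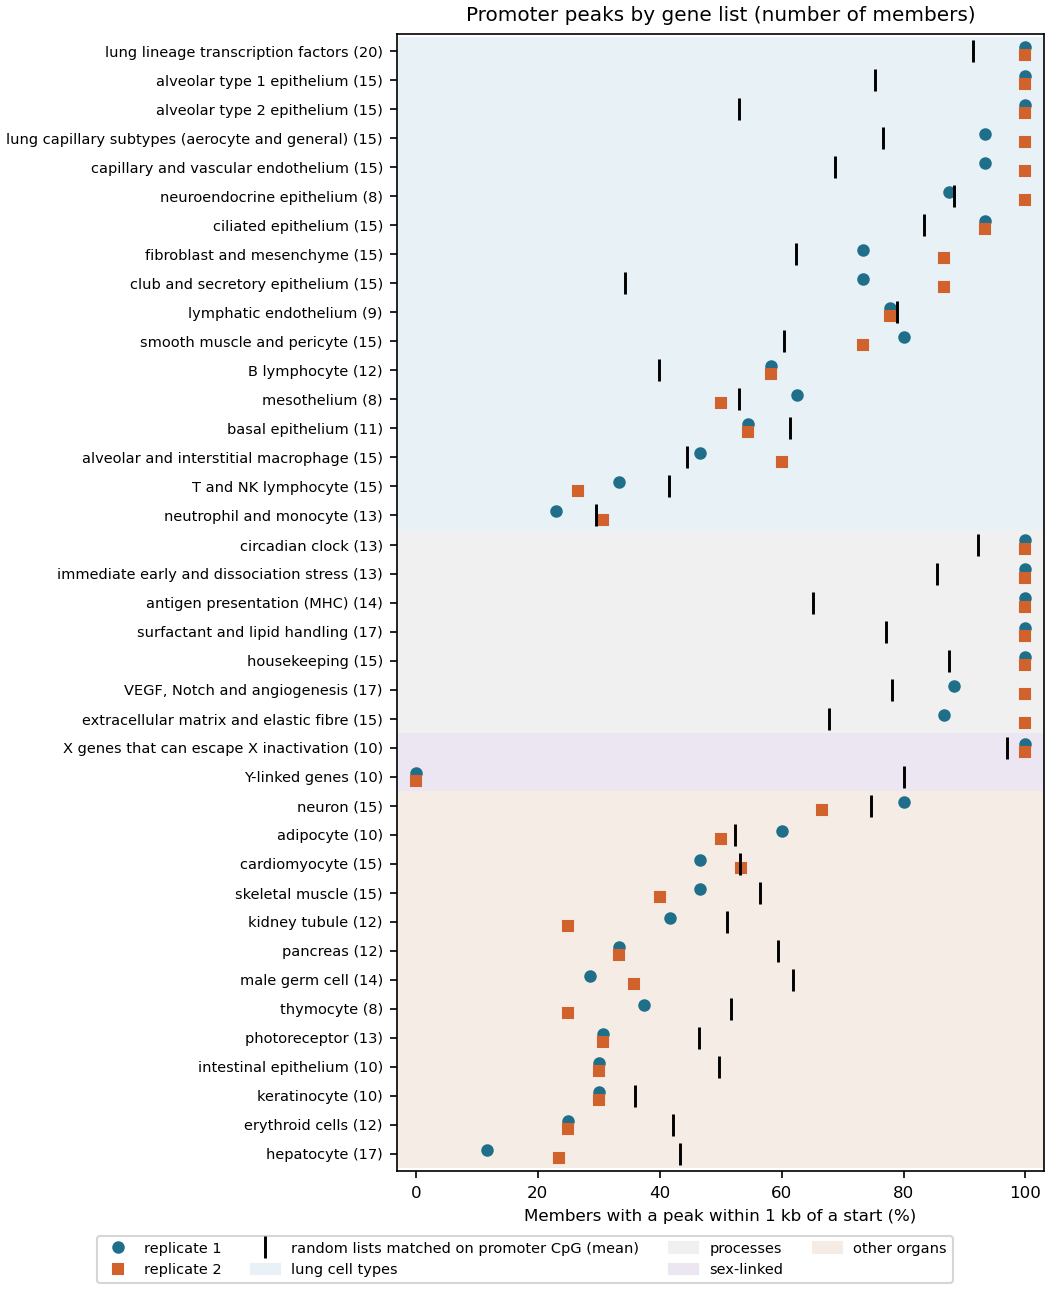
Percent of the members of each gene list with a peak within 1 kb of a transcription start (x axis), for every list but the 3 Hox lists (y axis, number of members in brackets), in replicate 1 (circles) and replicate 2 (squares), with vertical ticks for the mean of 10000 random lists matched on promoter CpG, averaged over both replicates, and background shading for the kind of list. Every member of the alveolar type 1, alveolar type 2 and lung transcription factor lists was open in both lungs, and none of the 10 Y-linked genes was.

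Process lists were open almost throughout. All 17 genes for surfactant and lipid handling had promoter peaks in each lung, against a random mean of 13.1, led by the sterol regulators Srebf2 (9.25 ± 1.79) and Srebf1 (6.81 ± 0.227). All 14 genes of antigen presentation were open against 9.12 and 9.11, led by the class I gene H2-D1 (14.2 ± 1.21), then H2-DMa beside Brd2, and Psmb9 and Tap1, which share a promoter. All 13 immediate early and stress genes were open, against a random mean of 11.1 in each lung. Jun stood at 14.5 ± 1.17, Atf3 at 12.6 ± 1.66 and Jund at 11.8 ± 1.88. The median of this list, 41.5 ± 3.31 peaks per 100 kb, was the highest of the 42 lists. All 13 clock genes were open, led by Nr1d1 (13.2 ± 3.83), Per1 (12.5 ± 2.76), Nr1d2 (12.3 ± 2.30) and Tef (12.2 ± 1.37). VEGF, Notch and angiogenesis genes were open for 15 and 17 of 17, against a random mean of 13.3 in each lung. The Notch target Hey2 stood at 9.42 ± 0.106 and the receptor gene Notch4 at 8.96 ± 0.977. Matrix and elastic fibre genes were open for 13 and 15 of 15, against 10.2 in each lung, with Ltbp4 at 4.83 ± 0.672 and elastin (Eln) at 3.83 ± 0.45. All 15 housekeeping genes were open, against a random mean of 13.1 in each lung, with the ribosomal gene Rplp0 at 14.9 ± 0.184.

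Promoters of Hox paralogues 1 to 5 were open most often, and those of paralogues 9 to 13 least often. Paralogues 1 to 5 had promoter peaks for 11 of 15 genes in replicate 1 and 13 of 15 in replicate 2, paralogues 6 to 8 for 5 and 4 of 8, and paralogues 9 to 13 for 4 of 16 in each lung. Random lists with the same CpG content gave 12.7, 6.93 and 14.6 in replicate 1. Paralogues 1 to 5 were at percentiles 10.0 (replicate 1) and 58.8 (replicate 2) of such lists, near random. Paralogues 6 to 8 were at 3.13 and 0.34, and the last group was at percentile 0 in each lung. Among the highest promoter peaks were those of Hoxa7 (3.65 ± 0.708, SD, n = 2), Hoxa5 (3.50 ± 0.787), Hoxa4 (2.99 ± 0.781), Hoxb5 (2.83 ± 0.806) and, among the last group, Hoxa10 (1.94 ± 0.584). Hoxa9, Hoxa11 and Hoxa13 had none, nor had Hoxb8, Hoxc8, Hoxd3, Hoxd4 and Hoxd8. A peak beside the end of the Hoxa13 gene, away from its start, stood at 4.02 in replicate 1 and 2.35 in replicate 2. The peak counted for Hoxc10 lies beside a start of Hoxc5. Within gene bodies and 2 kb flanks, paralogues 1 to 5 held 17.8 and 13.5 peaks per 100 kb, paralogues 6 to 8 held 19.2 and 25.5, and paralogues 9 to 13 held 8.42 in each lung. By this measure paralogues 6 to 8 were the densest in both lungs. Hox domains can overlap, as the Hoxa3 model spans Hoxa4 and Hoxa5, so a peak can be counted more than once. The difference between the ends was 7.22 ± 3.09 (SD, n = 2), 9.40 in replicate 1 and 5.04 in replicate 2, and it became 3.13 with the shorter peak list. In the Hoxd cluster the order was the opposite, with 4.42 peaks per 100 kb in paralogues 1 to 5 of each lung against 10.2 and 7.67 in paralogues 9 to 13.

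**Figure D3:**
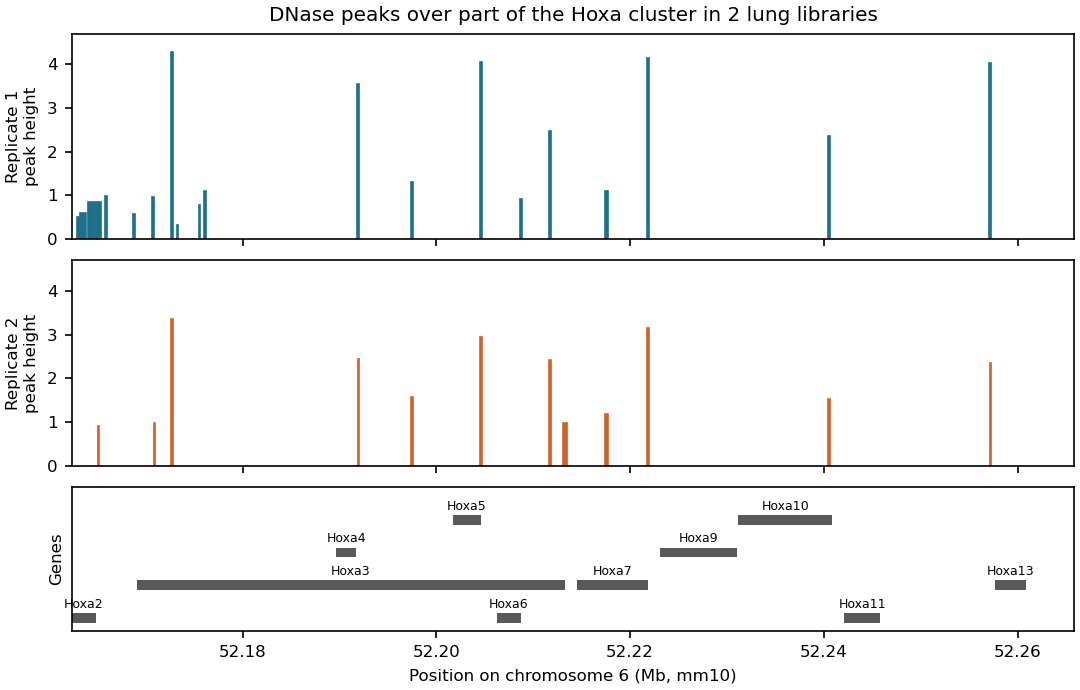
Peaks of replicate 1 (top) and replicate 2 (middle) over part of the Hoxa cluster on chromosome 6 (x axis, Mb of mm10), with bar height giving the deposited signal of each peak and bar width its extent, above the gene models (bottom). The tallest bars at gene starts stand at Hoxa4, Hoxa5 and Hoxa7, and the starts of Hoxa9, Hoxa11 and Hoxa13 have none. Bars of similar height also stand inside Hoxa3 and beside the end of Hoxa13, away from the starts of these genes.

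The X chromosome carried few peaks for its size. It held 3569 peaks in replicate 1 and 3745 in replicate 2, and its density per Mb was 0.370 and 0.377 of the median autosome (mean 0.373 ± 0.00537, SD, n = 2). Per coding gene the ratio was 0.541 and 0.546, and 52.6% ± 0.224 of X-linked coding genes had a promoter peak against 71.5% ± 0.0782 of autosomal ones. The low density was stronger for high peaks, with a ratio of 0.247 for the higher 50% of peaks. All 10 X-linked genes of the list that can escape X inactivation were open in each lung. For its 6 coding members, random lists matched on CpG content gave 5.84 and 5.81, so this was near random (percentiles 57.5 and 59.0). The histone demethylase gene Kdm6a led (15.7 ± 1.70), then the non-coding Ftx gene (8.25 ± 0.612), Kdm5c (8.07 ± 0.633) and Utp14a (6.98 ± 1.43). None of the 10 Y-linked genes, Ddx3y, Eif2s3y and Kdm5d among them, had a promoter peak in either animal, both of which are labelled female.

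The coding genes with the most peaks were long genes and read-through models. Gm20388, a model that spans 4434.88 kb of chromosome 8 and many other genes, held 674 and 648 peaks, and Fgfr2, a receptor of lung branching whose model spans 2960.90 kb of chromosome 7, held 302 and 319. Gse1 (108 and 102 peaks) lies inside the span of Gm20388 and had the highest density of the 10, with 29.0 and 27.4 peaks per 100 kb. The others were Gm37240, the phosphodiesterase gene Pde4d (97 and 109 peaks), Nav2 (101.5 ± 9.19, SD, n = 2), the transcription factor genes Foxp1 (77.5 ± 2.12), Rora (75.5 ± 3.54), Zfhx3 (75.5 ± 12) and Mecom (74.0 ± 7.07).

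Of the 10 highest shared peaks away from promoters, 4 lay in sequence with further copies on the chromosomes. The highest by mean rank lay in an exon of Lars2 (chromosome 9, 123461901 to 123462100) with heights of 40.6 and 22.9. The next lay in an exon of Cers5 with Cox14 as the nearest start (chromosome 15, 99735661 to 99735920; 31.8 and 26.7), 109640 bases from Gm8797 (chromosome 3, 5860361 to 5860530; 28.5 and 27.8) and near the X-linked Pak3 (143482981 to 143483140; 44.9 and 18.5). Those at Il31ra, Igf2bp3 and Ubqln1 had mean heights of 23.0, 25.4 and 16. Of these 7, the peaks at Lars2, Gm8797, Il31ra and Igf2bp3 have 4, 15, 6 and 2 further copies on the chromosomes. The last 3 had no further copy at 90% identity and lay near the cytokine signalling inhibitor gene Socs3 (chromosome 11, 117963461 to 117963700; 12.5 and 14.9), inside Mxi1 (chromosome 19, 53314221 to 53314420; 12.1 and 15) and inside the clock gene Nr1d1 (chromosome 11, 98773761 to 98774200; 11.5 and 16.1).

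Footprints lay in most open regions and in nearly all of the strongest. The deposited footprints numbered 377652 in replicate 1 and 367594 in replicate 2 (mean 372623 ± 7112, SD, n = 2), with a median width of 10 bases. Of these, 87.5% and 86.5% lay inside peaks, and 82.0% and 77.9% of peaks held at least 1. Promoter peaks held 2.97 and 2.92 footprints on average and distal peaks 2.13 and 1.95. Among the lowest 10% of peaks by height 37.2% and 23.1% held a footprint, and among the highest 10% 99.96% in each lung did. In 106334 regions open in both animals, 55.1% of the footprints of replicate 1 and 58.3% of those of replicate 2 touched a footprint of the other. Shifts within these regions gave 24.4% and 25.7%, so the overlap was 2.25-fold and 2.27-fold above that of shifted footprints.

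Footprints were enriched in the motifs of a limited set of DNA-binding proteins. The motif of NRF1, an activator of mitochondrial and housekeeping genes, was 126 ± 50.5 times (SD, n = 2) as dense inside footprints as in the rest of the same peaks, and that of CTCF, the insulator and loop anchor protein, 35.5 ± 5.37 times. The cyclic AMP response element (CRE) followed with 17.6 ± 1.962, and the motif of REST, the repressor of neuronal genes, with 16.8 ± 9.37 (23.4 in replicate 1 and 10.2 in replicate 2). NFI motifs reached 11.8 ± 0.0326, USF-type E-boxes 10.7 ± 1.80, RFX motifs, bound by the ciliogenesis factors, 7.09 ± 0.285, and C/EBP motifs 6.82 ± 1.42. Of 34 motifs, 12 were at least 2 times as dense in footprints in both lungs; the other 4 were those of SP and KLF factors, YY1, NFY and HNF1, the last with only 2 and 4 matches inside footprints and an interval of 0.308 to 32.2 in replicate 1. None of 32 reversed motifs, used as a composition control, reached 2 in both lungs. The REST motif and the SP and KLF motif had no reversed value. Reversed, the CRE and E-box sequences hold no CpG, so for them the control does not cover CpG content. For the YY1 motif the reversed sequence reached a mean of 4.24 ± 3.39, which overlaps the 6.16 ± 0.373 of the motif itself.

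Another 12 motifs were less dense in footprints than around them in both lungs. FOX motifs, bound by the lung factors of the forkhead family, had the lowest ratio at 0.395 ± 0.0514, followed by glucocorticoid receptor sites (GR) at 0.492 ± 0.00417, CRX at 0.516 ± 0.0174, ZEB at 0.662 ± 0.0527, POU2 at 0.667 ± 0.0338, GATA at 0.721 ± 0.205, SOX at 0.751 ± 0.0335 and TBOX at 0.762 ± 0.00737. RUNX (0.858 ± 0.0113), RBPJ (0.914 ± 0.0808), TEAD (0.921 ± 0.0534) and SPI1 (0.95 ± 0.0316) were close to 1. Footprints were richer in G and C (60.6% and 59.5%) than the rest of the peaks (53.0% and 52.4%), and the reversed FOX motif also lay below 1, at 0.640 ± 0.00188. Reversed motifs were lower than the motifs themselves for GATA (0.409), SOX (0.562), RUNX (0.617), SPI1 (0.624), TEAD (0.638) and, slightly, POU2 (0.630). They were higher for GR (0.576), CRX (0.712), ZEB (0.715), TBOX (0.885) and RBPJ (1.04), as for FOX. A ratio under 1 therefore does not by itself show that footprints lack a motif beyond base composition.

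Distal peaks, compared with windows 10 kb away, held another set of enriched motifs in addition. REST sites were the most enriched, with 161 matches in the distal peaks of replicate 1 against 2 in the windows, a ratio of 80.2 (95% interval 21.9 to 668.2), and with 109 against 0 in replicate 2, a ratio of 36.2 when the windows are set to 3 counts and of at least 28.9 by the lower end of the exact 95% interval. NFI motifs followed with 15.4 ± 6.10, CTCF with 11.3 ± 1.69, C/EBP with 8.22 ± 0.423 and NRF1 with 5.40 ± 2.47 (SD, n = 2). Altogether 16 motifs were at least 2 times as dense in distal peaks in both lungs, and none of 29 reversed motifs was. The REST, NFI, NRF1, YY1 and SP and KLF motifs, all among the 16, had no reversed value, so the control does not cover them. The limit on CpG content given for footprints holds here too. For 6 of the 16 this held in distal peaks and not in footprints. These were the ETS motif (2.80 ± 0.0119), glucocorticoid receptor sites (2.79 ± 0.830), the MYOD-type E-box (2.49 ± 0.267), the stress-responsive AP1 motif (2.38 ± 0.10), the myeloid SPI1 motif (2.23 ± 0.0553) and STAT sites (2.09 ± 0.00673). The motif of the NKX2 family, to which the lung regulator Nkx2-1 belongs, reached 1.69 ± 0.0951. POU2, ZEB, CRX, IRF, TBOX, SOX and SRF motifs were below 1 in both lungs, from 0.684 ± 0.0396 for POU2 upward. Distal peaks had 50.9% and 50.4% G and C against 44.7% and 44.5% in the windows.

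**Figure D4:**
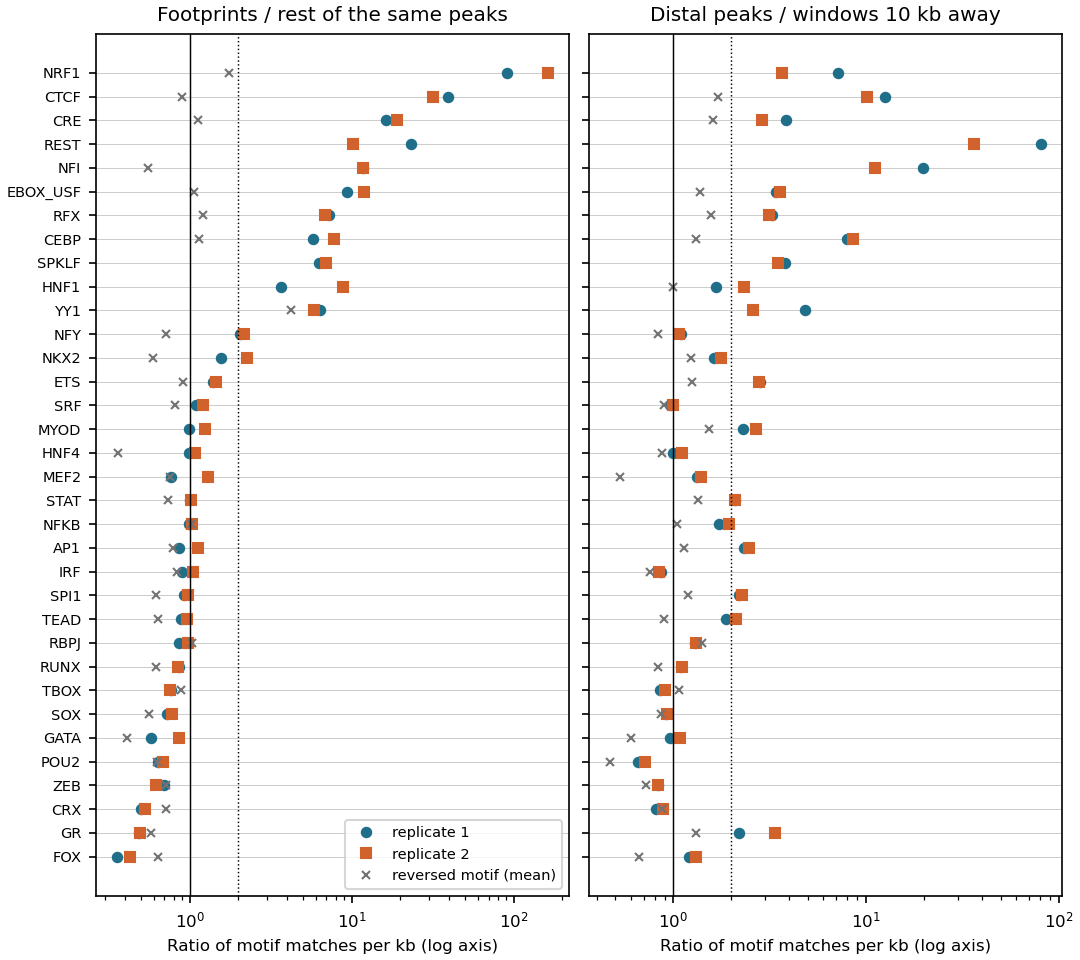
Ratio of motif matches per kb (x axis, log scale) for 34 motifs (y axis) in footprints over the rest of the same peaks (left) and in distal peaks over windows 10 kb away (right), for replicate 1 (circles) and replicate 2 (squares), with crosses for the mean of the reversed motif where it has a value; the solid line marks 1 and the dotted line 2, and REST and HNF1 in distal peaks of replicate 2 are computed with 3 counts in the windows, which held none. NRF1, CTCF, CRE, REST and NFI lie above 10 in footprints of both lungs, and FOX lies lowest.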

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

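In this part the test on the promoters of Y-linked genes was chosen only after its result was seen, and the search for copies was planned before. Both animals are labelled female, yet the deposited lists hold 44 peaks on the Y chromosome in replicate 1 and 53 in replicate 2. The peaks were low, with median heights of 0.277 and 0.144 against 0.570 and 0.6 over all peaks, and 29 in each animal touched a Y peak of the other. Male DNA in a share large enough to open promoters to the call would give peaks at Y-linked genes that are active in most male tissues. Of the 10 Y-linked genes listed, 0 had a promoter peak in either animal, so the tables argue against such a share. Not all of the 10 are active in most male tissues, so this rests on fewer than 10 genes, Ddx3y, Eif2s3y and Kdm5d among them. Reads shared with copies elsewhere could be a source: 77.3% of the Y peaks of replicate 1 and 71.7% of those of replicate 2 have a copy on X or an autosome, against 42.5% and 41.5% of 200 random Y windows. That share lies under the 80% set beforehand as decisive, so this explanation stays open, for the peaks without a copy above all. No biological explanation was tested, since the design names no difference in sex.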

How the results depend on the processing

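Of 71 recomputed values of the comparisons, 47 moved by less than the spread between the animals (for rho, its 95% interval) or, for counts, stayed within 1.5 times, 24 moved further and none changed direction. The 47 include all 26 values that leave out a replicate, which with 2 replicates cannot move further except for counts; of the other 45, 21 stayed. The shorter list gave a peak number of 93537, an overlap of peaks of 80.5%, a rho of 0.901, a promoter share of 34.5%, a lung minus other-organ difference of 4.16 peaks per 100 kb, a Hox difference of 3.13 and an X to autosome ratio of 0.346. The higher 50% of peaks gave 85.6% overlap, a rho of 0.856, a promoter share of 38.8%, a difference of 3.64 peaks per 100 kb and an X ratio of 0.247. Requiring 50% of both intervals gave 64.5% overlap of peaks, a rho of 0.914 and 41.8% overlap of footprints. The higher 50% of shared peaks gave 67.7% overlap of footprints, and both of these stand against 56.7% in the report. Promoter windows of 500 bases and 2 kb gave shares of 22.3% and 36.1%, and 2 kb a lung minus other-organ difference of 31.9 percentage points. Of the alternatives chosen after seeing the data, basic transcript starts gave a share of 24.8%, and matching on CpG content left a lung minus other-organ difference of 30.1 points. Flanks of 2 kb and 50 kb gave 7.57 and 2.97 peaks per 100 kb, and densities per coding gene an X ratio of 0.544. Windows, flanks and overlaps act by their construction; for the other values the cause was not tested. Among counts of list members with a promoter peak 183 of 210 recomputed values stayed within 1.5 times, 26 fell below it and 1 rose above; another 84, which leave out a replicate, all stayed. Among promoter heights of named genes 684 of 1170 stayed within the spread between the animals and 467 of the others were lower, and among motif ratios 64 of 102 did, with 18 higher, 19 lower and 1 reversed. The STAT ratio in footprints, 1.02, became 0.980 with 50-base flanks as background. With those flanks MEF2 went from 1.03 to 0.978 and IRF from 0.977 to 1.01, which also crosses 1 but by less than their spread between the animals. Leaving out each replicate in turn gave 140311 to 145721 peaks, promoter shares of 27.6 to 29.9%, 15369 to 15395 genes, list differences of 35.6 to 40.5 points and 5.99 to 6.24 peaks per 100 kb, a Hox difference of 5.04 to 9.40, X ratios of 0.370 to 0.377, 367594 to 377652 footprints, 12 to 13 and 16 to 18 motifs, and covered bases of 48.0 to 53.6, 38.8 to 43.3 and 30.9 to 34.3 Mb at the 3 FDR limits. With 2 replicates these ranges lie within 1 SD of the mean by construction. The 2 alternatives chosen beforehand on footprint scores were not run because the deposited footprints carry no score.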

Other observations

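In this part all comparisons of heights between the animals were chosen after the data were seen, and the tests on epithelium against stroma and on the time of day were chosen only after their results were seen. The tests on copies, mitochondrial DNA, height and base composition were set down before their results.

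Distal sites with different motifs differed in height between the 2 lungs. Of 33 motifs found in at least 20 of the peaks, 19 had a median outside all 1000 random sets of peaks matched on height, 3 of them lower in replicate 2 and 16 higher, most by little. Relative to the median of 76696 shared distal peaks, the 100 that hold a REST motif were lower in replicate 2 by a median log2 ratio of -0.84, the 8249 with a CTCF motif by -0.71 and the 128 with an NFI motif by -0.31. The 261 peaks with a glucocorticoid receptor site were higher in replicate 2 by 0.47, those with an NKX2 motif by 0.22, those with C/EBP motifs by 0.21, those with TEAD motifs by 0.20, those with a FOX motif by 0.17, those with a MEF2 motif by 0.15 and those with GATA and AP1 motifs by 0.14 each. The other 8 (EBOX_USF, NFKB, HNF4, STAT, NFY, RBPJ, ETS and SPI1) were higher by 0.06 to 0.14. The random sets were matched on height and not on base composition, so a part of base composition in these differences was not tested. These are differences between 2 single animals, with no further animal to show which is usual.

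Promoter heights also differed between the lungs for some of the gene lists. Relative to the median of 15031 coding genes open in both lungs (0.14 on the log2 scale, replicate 2 over replicate 1), the 15 alveolar type 2 markers were higher in replicate 2 by a median of 0.45, with 14 of 15 above the median. Sftpc, the surfactant protein C gene, stood at 1.31 in replicate 1 and 2.93 in replicate 2, and Lamp3 at 0.357 and 0.906. Lung lineage transcription factors were higher by 0.22, with Nkx2-1 at 2.47 and 4.18, and matrix and elastic fibre genes by 0.24. Neuron markers were lower in replicate 2 by a log2 ratio of -0.77 and neuroendocrine markers by -0.70, with Snap25 at 2.31 and 1.23 and Chga at 1.39 and 0.948. The peaks counted for Snap25 and Chga lie 783 and 175 bases from the nearest start. Whether promoter peaks of these 2 lists hold a REST motif, like the distal peaks above, was not tested. These lists, 5 of 27, namely type 2, lineage factors, matrix, neuron and neuroendocrine, lay outside the middle 95% of random lists matched on height. About 5% of lists would do so if the genes of a list varied independently between the libraries, which was not tested. Lists also share members, so 5 of 27 against 5% is a description and not a test. With only the genes whose highest peak is the same in both animals, 25 lists could be compared and the same 5 lay outside. The matrix list was only just outside, at 0.20 and percentile 97.9. It also counts 1 peak, shared by Col4a1 and Col4a2, as 2 members, and their value is the list median of 0.24.

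Several technical sources were tested for that difference between lists. A difference that depends only on how high a peak is was argued against: 3 of the 14 lung lists with enough members lay outside the height-matched range, and the type 2 list lay above all 10000 random lists. The bound set beforehand, over 20% of all 17 lung lists, was not met by these 3, and the verdict rests on the type 2 list, a criterion adopted after the result was seen. A bias of base composition was argued against as the whole source, since 5 of the 5 lists stayed outside when random lists were matched on height and CpG ratio and again on height and GC content. A different share of epithelium in the 2 pieces of lung was neither shown nor excluded as a part of it. The 4 epithelial lists chosen (type 2, type 1, club and ciliated) exceeded 2 stromal lists (fibroblast and smooth muscle) by 0.19 on the log2 scale, at percentile 87.7 of matched lists. That lies inside the middle 95%, which the criterion written for this test counts against the explanation. A value inside that range does not exclude a smaller difference in share. The mesothelium list had too few members open in both. Basal and neuroendocrine epithelium had enough but were not among the 4. They stood at 0.038 and -0.70, so the excess depends on which epithelial lists are taken. No other biological explanation was tested, since the design names no difference between the animals.

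The 10 highest shared distal peaks were tested for reads that belong elsewhere. Reads from mitochondrial DNA were argued against, since 0 of the 10 matched the mitochondrial genome. The search found 16 of 16 test windows, but these were cut from the mitochondrial genome itself and only show that the search ran. None of the 140311 peaks of replicate 1 or the 145721 of replicate 2 matched it either, so this result does not set the 10 apart. Reads shared with other copies on the chromosomes may raise some heights, and this stays open: 4 of the 10 peaks, at Lars2, Gm8797, Il31ra and Igf2bp3, have a further copy, between the bounds set beforehand (at least 5, or fewer than 2). The other 6 had none at 90% identity over 80% of the peak, but shorter or less similar copies were not searched. No biological explanation was tested for these peaks.

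A hypothesis of circadian time was tested because the promoter heights of Nr1d1 and Per1 were larger in replicate 2 (15.9 and 14.5) than in replicate 1 (10.5 in each). For Per1 these are 2 different peaks, at 69098781 to 69098980 of chromosome 11 in replicate 1 and at 69094741 to 69095260 in replicate 2, so they are no rise of a single peak, and only the Nr1d1 values come from the same peak. If the lungs had been collected at different times of day, clock genes that peak together could move apart from Arntl, Clock and Npas2. The median log2 ratio of the former 8 genes minus that of the latter 3 was -0.074, at percentile 24.1 of matched lists, or -0.15 at percentile 14.8 with Per1 left out for that reason, and Arntl itself was higher in replicate 2. Percentile 24.1 lies inside the middle 95%, which the criterion written for this test counts against a difference in time. With 3 genes in an arm the comparison does not exclude such a difference, which stays untested by any label.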
